A study of Mus musculus with 6 samples.

How the data were processed

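RNA was measured in 6 MC38 tumour libraries, 3 per group, from mice given Lipo-adjuvant or the iPM nanovax. Total RNA was extracted with an MJZol kit and libraries were made with a stranded mRNA kit, per the labels' protocols, although the labels list the molecule as genomic DNA. Reads were trimmed with fastp and aligned with HISAT2 to GRCm39, per the submitters' processing notes. Their versions, the quantifier, the annotation release and the use of strand are not given in the sources used here. The table the authors deposited is named as raw counts, but its values are TPM. They are not whole numbers, each library sums to the same total within rounding, and the lowest values fall with gene length. TPM keeps no sequencing depth, so no counting interval or lower limit is given. The values are shares of each library, so a few genes that take more of it lower all others. An exact 0 is written as listed at 0. The table has 57010 genes, with symbols and identifiers as it gives them. It also holds 3 columns of per-library values that match no sample analysed here, and these were not used. No coordinates are given, because the reference at hand, GENCODE M21, uses another genome build. It served only for the length and overlap of the genes that passed.

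A count-based test had been chosen before the data were examined. Because the values are TPM, it was replaced by limma 3.58.1 (R 4.3.3) on log2(TPM + 1) with a mean-variance trend and no covariate. Genes with at least 1 TPM in at least 3 libraries were tested, which left 13433 (11851 protein-coding). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. A difference is vaccine minus adjuvant on the log2(TPM + 1) scale, which understates the change of low genes. Means and SDs are of TPM over the 3 libraries of a group, given as adjuvant and then vaccine where 2 stand together.

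The 31 gene lists, with 415 members of which 413 were found in the table, were fixed before the data were examined. Lists with at least 3 tested genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the lists. Beside this stand camera with an estimated correlation, fry, and the count of members that pass over all genes and adjusted over the list alone. The level of a list in a library is the mean log2(TPM + 1) of its tested genes, compared by an exact two-sided permutation test. Its difference without each library and its rank correlation with Ptprc were added after the levels were seen. KEGG sets of 10 to 300 tested genes, 299 in all, were taken from the pathway annotation in the deposited table after it was seen, and were tested in the same way.

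The genes named were set by a rule written before the data were examined. Of the genes with a symbol that passed, did not overlap between groups and had a mean of at least 1 in the higher group, the 12 with the largest change in each direction were to be named, leaving out predicted genes and pseudogenes. As fewer than 10 genes passed, the 10 with the smallest unadjusted p in each direction under the same conditions were to be named too. Some genes that these rules select are left out of the text and figures. In each list up to 4 members that pass were to be named, or otherwise the 2 with the smallest p. Others were named after their values were seen. These are Gm45236, Acta1 and Ptprc, members of the KEGG sets, and further members of the inflammatory cytokine list.

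The fit was tested on simulated data for this comparison with 13433 genes, of which 200 were changed in each of 10 draws. It recovered 62.9% of genes changed by a log2 size of 1 and 90.4% of those changed by 2, and 4.96% of its calls were false. With independent genes, camera made 5 calls over 31 lists with no effect and 10 draws, and called a shifted T cell list in 10 of 10 draws. The noise in both simulations was independent between genes. In the data the lists that passed had estimated correlations of 0.276 to 0.956. The draws therefore cannot show how often camera calls such lists falsely. The alternatives were 2 scalings, 2 filters on low values, 2 pseudocounts (0.1 and 5), library quality weights, a replicate block, no variance trend, protein-coding genes alone, the skeletal muscle level as a covariate, leaving out each library in turn or adjuvant 3 and vaccine 1 together, and other set tests. Figures were drawn with matplotlib.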

Results

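RNA was sequenced from MC38 tumours grown under the skin of mice. MC38 is a mouse colon adenocarcinoma cell line. The mice had been immunised on days -22, -15, -8 and -1, received tumour cells on day 0, and were killed on day 28. The 3 libraries of the adjuvant group (adjuvant 1 to 3) came from mice given Lipo-adjuvant, and the 3 of the vaccine group (vaccine 1 to 3) from mice given the iPM nanovax. The comparison asks which genes differed in the tumour tissue after the vaccine, with the adjuvant group as the control. The labels do not say whether the replicates are separate animals, so p-values measure only the spread between these libraries, which may be technical. The deposited values were TPM, which keep no sequencing depth, so the depth is unknown. Between 21037 and 22052 genes per library were above 0, and 13189 to 13652 had at least 1 TPM. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.985 to 0.988 within the adjuvant group, 0.984 to 0.989 within the vaccine group and 0.981 to 0.989 between groups.

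Xlr, an X-linked lymphocyte-regulated gene, fell from 11.8 ± 1.09 TPM in the adjuvant group to 1.79 ± 0.393 TPM in the vaccine group (SD, 3 libraries each). Its log2 difference, on the log2(TPM + 1) scale used for all genes here, was -2.21 (SE 0.160, limma adjusted p = 0.0104). The other members of the Xlr family, which resemble it in sequence, were listed at 1.61 TPM or less in every library. The other gene that passed was Gm45236, an uncharacterised transcript, which was named here after its values were seen. It was listed at 6.88, 12.55 and 10.04 TPM in adjuvant 1, 2 and 3 and at 0 in all 3 vaccine libraries (limma adjusted p = 0.00944). In GENCODE M21 it has 229 exonic bases and lies opposite Gde1, and how the quantification used strand is not given in the sources used here. These were the only 2 of 13433 genes past an adjusted p of 0.05, both lower in the vaccine group. At an unadjusted p under 0.05 there were 1638 genes, 1282 higher and 356 lower, where chance would give 672 on average. The 2 groups did not overlap for 2476 genes, or 18.4%, where chance gives 10% on average. Genes vary together, so a single grouping can stray far from such averages. Other splits of the 6 libraries into 3 and 3 gave 121 to 1469 genes at an unadjusted p under 0.05. The median log2 difference of all genes was 0.0925 on the TPM scale and -0.000946 after median-of-ratios scaling, which moved the split at an unadjusted p under 0.05 to 655 higher and 718 lower (47.7% higher, against 78.3%). The count of calls rested on single libraries, while the log2 difference of Xlr was -2.27 to -2.085 without any 1 library. Without adjuvant 1, 44 genes passed (31 higher, 13 lower), of which only Xlr was shared. Without adjuvant 2, 1 other gene passed and Xlr had an adjusted p of 0.0581. Without adjuvant 3, limma called 0 genes, with 789 at an unadjusted p under 0.05, and Xlr had an adjusted p of 0.216. Gm45236 was below the filter on low values whenever an adjuvant library was left out. With no filter on low values the limma adjusted p was 0.0859 for Xlr and 0.0724 for Gm45236. With the replicate numbers as a block it was 0.198 for both. Their log2 differences stayed at -2.208 and -3.401 in these fits.

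Among the genes with the smallest p-values, those higher in the vaccine group included enzymes of cholesterol synthesis, although none passed over all genes. Hmgcs1, which makes HMG-CoA for the mevalonate pathway, was at 48.8 ± 10.3 TPM in the adjuvant group and 130.3 ± 6.42 TPM in the vaccine group (log2 difference 1.42, SE 0.15, limma adjusted p = 0.0731). Sqle, Msmo1 and Cyp51, which act later in cholesterol synthesis, had log2 differences of 1.10, 1.03 and 1.04. Elovl6, a fatty acid elongase, had a log2 difference of 1.20. The others named here are the cytokine gene Il1b and the immunoglobulin segment Igkv1-135, which was at 0.697 ± 0.259 and 3.80 ± 0.773 TPM and belongs to a family of similar sequences that can share reads.

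The genes lower in the vaccine group with the smallest p-values after Xlr did not pass over all genes. Angptl4, an inhibitor of lipoprotein lipase, was at 74.1 ± 13.6 TPM in the adjuvant group and 26.5 ± 4.29 TPM in the vaccine group (log2 difference -1.45, SE 0.166, limma adjusted p = 0.103). Pi16 and Fbln1, which are expressed in fibroblasts, had log2 differences of -1.73 (adjusted p = 0.145) and -0.81 (adjusted p = 0.119). The stress-response genes Ddit3 and Gadd45a had log2 differences of -0.93 and -0.84, with adjusted p-values of 0.184 and 0.189. Id3, Pgf and the zinc exporter Slc30a1 had log2 differences of -1.16, -0.98 and -0.85, each with an adjusted p of 0.189. Defb25, a beta-defensin gene, was listed at 1.49, 1.82 and 3 TPM in adjuvant 1, 2 and 3 and at 0 in all vaccine libraries (adjusted p = 0.119).

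The KEGG set of steroid biosynthesis rose in the vaccine group, with 13 of its 15 measured genes higher and a median log2 difference of 0.588 (limma's camera with a preset correlation, adjusted p = 7.92e-06, and 0.981 with an estimated correlation). Of these genes 9 passed adjusted over the set alone, among them Lss, Fdft1 and Lbr. Terpenoid backbone biosynthesis, which holds the mevalonate pathway, also rose, with 18 of 21 genes higher and a median of 0.27 (adjusted p = 4.81e-05, and 0.981 with an estimated correlation), and 8 passed adjusted over the set alone. Idi1, which isomerises isopentenyl diphosphate, was at 36.5 ± 10.9 and 97.2 ± 10.8 TPM, and Mvd was at 15.2 ± 2.29 and 29.9 ± 3.34 TPM. These sets came from the pathway annotation in the deposited table and were chosen after it was seen. In all, 9 of 299 sets passed, and none did with an estimated correlation (smallest adjusted p = 0.981) or with fry (smallest adjusted p = 0.235). The others that rose were C-type lectin receptor signalling (75 of 90 genes higher), viral protein interaction with cytokines and their receptors (42 of 51) and the Fanconi anaemia pathway (43 of 50). Those that camera placed below the other genes were the ribosome (88 of 128 genes lower), protein digestion and absorption (30 of 43), ECM-receptor interaction (35 of 51) and oxidative phosphorylation (67 of 118). The oxidative phosphorylation set itself did not fall, with a median log2 difference of -0.0189 against 0.0925 for all genes and an exact permutation p of 0.8. The groups also overlapped in the level of protein digestion (exact permutation p = 0.4) and of ECM-receptor interaction (0.3), but not of the ribosome (0.1). The 80 ribosomal protein genes took 21.6% ± 0.07 of the TPM in the adjuvant group and 19.8% ± 0.0964 in the vaccine group (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3). Without adjuvant 2, 34 sets passed, and without vaccine 1, 42 did. Steroid biosynthesis, terpenoid backbone biosynthesis and the ribosome passed without any 1 library. The oxidative phosphorylation set did not pass without adjuvant 3 (adjusted p = 0.779), nor did the lectin and cytokine sets without vaccine 3 (adjusted p = 0.155 and 0.311). C-type lectin signalling also missed without adjuvant 1 (adjusted p = 0.0832), protein digestion without adjuvant 3 (0.0685) and ECM-receptor interaction without vaccine 3 (0.0551). When 1 library was left out, the Fanconi set passed only without vaccine 1 (adjusted p = 0.00761), and otherwise its adjusted p was 0.0517 to 0.168. Outside these fits, the C-type lectin, viral protein and Fanconi sets also missed with the stricter filter of 5 TPM (adjusted p = 0.0762, 0.0988 and 0.1048) and with quality weights (0.0501, 0.0751 and 0.0501). Protein digestion missed with no filter (0.0598), the Fanconi set on the protein-coding scale (0.0679) and with the muscle covariate (0.0617), and oxidative phosphorylation without adjuvant 3 and vaccine 1 together (0.955).

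**Figure D1:**
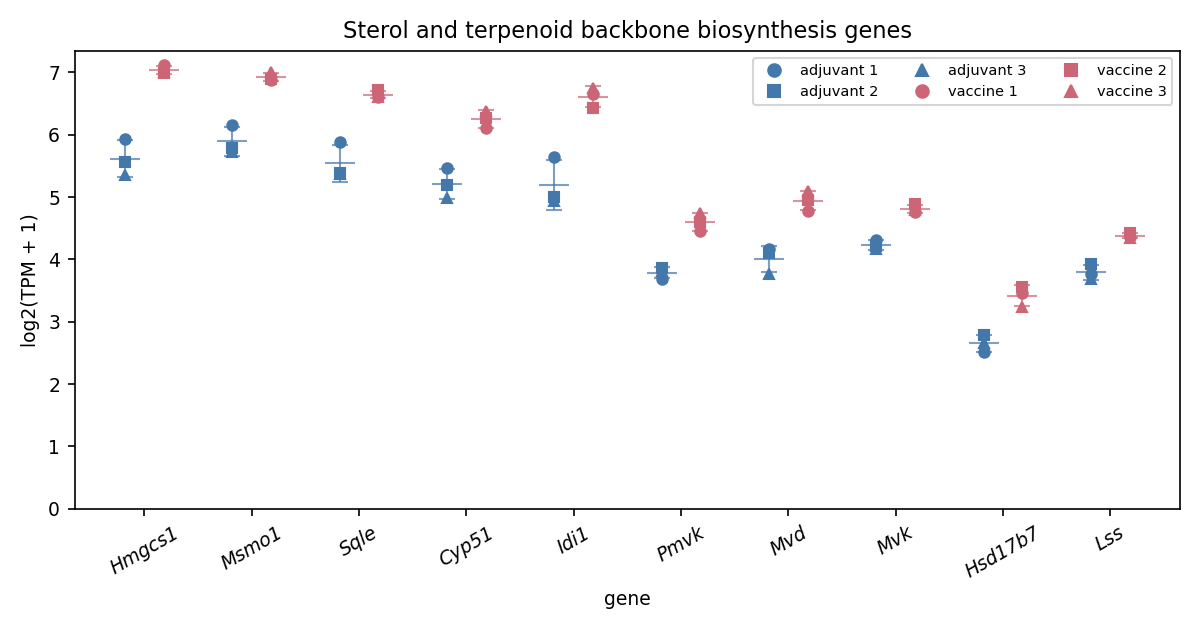
Level of 10 of the 12 genes with the smallest p in the steroid and terpenoid backbone biosynthesis sets, as log2(TPM + 1) on the vertical axis, for each library (points) with the group mean and SD (bars, 3 libraries per group). Every vaccine library lies above every adjuvant library in each gene shown, as for Hmgcs1 and Idi1.

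The inflammatory cytokine list rose in the vaccine group. All 11 of its measured genes were higher, with a median log2 difference of 1.32 (camera with a preset correlation, adjusted p = 1.23e-06). The call did not hold with an estimated correlation (adjusted p = 0.653), and fry gave an adjusted p of 0.0952. No member passed over all genes, and 8 passed adjusted over the list alone. Il1b, an inflammatory cytokine of myeloid cells, was at 1.62 ± 1.38 TPM in the adjuvant group and 17.2 ± 4.78 TPM in the vaccine group (log2 difference 2.88, SE 0.355, limma adjusted p = 0.104). Ccl2, a chemokine that attracts monocytes, was at 160.8 ± 74.2 and 491 ± 74.4 TPM (log2 difference 1.69, SE 0.292, adjusted p = 0.189). Ccl3 was at 2.82 ± 1.58 and 10.7 ± 3.61 TPM and Ccl7 at 35.1 ± 21.05 and 77.8 ± 5.34 TPM. The others past the threshold over the list alone were Il1a, Osm, Nos2 and Cxcl2, and Cxcl1, Ptgs2 and Ccl4 did not pass. The list mean per library was 1.99 to 2.61 in the adjuvant group and 3.24 to 4.02 in the vaccine group (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3).

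**Figure D2:**
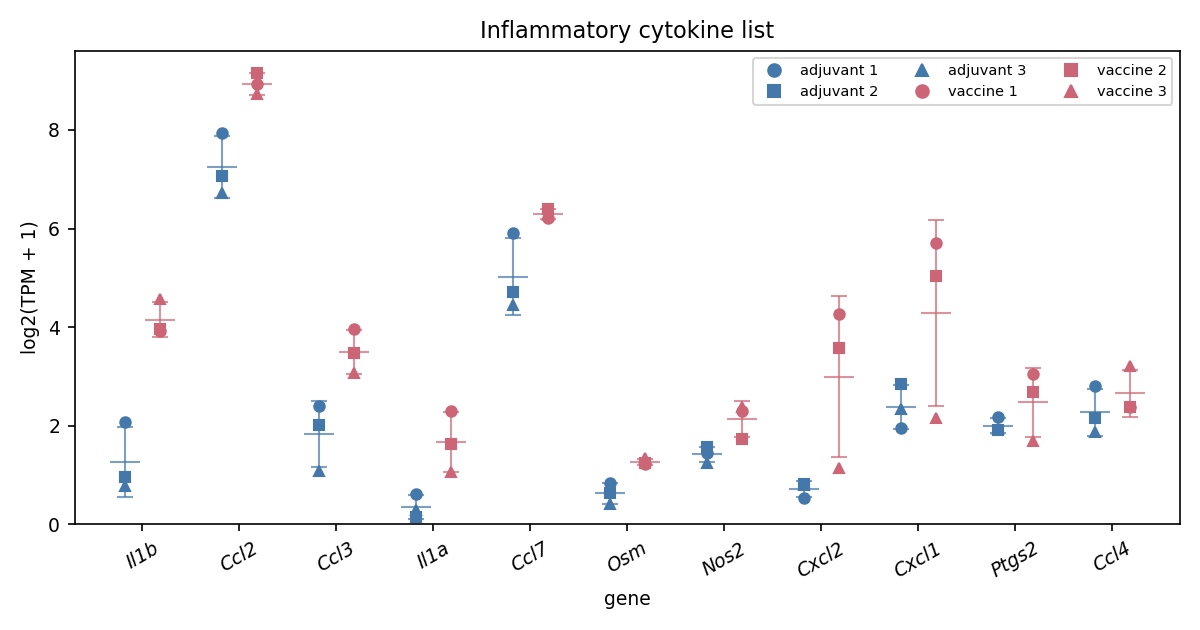
Level of the 11 measured genes of the inflammatory cytokine list, as log2(TPM + 1) on the vertical axis, for each library (points) with the group mean and SD (bars, 3 libraries per group). The libraries of the groups do not overlap for the 8 genes from Il1b to Cxcl2, and they overlap for Cxcl1, Ptgs2 and Ccl4.

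Genes induced by interferon gamma rose as a list, with all 17 measured members higher and a median log2 difference of 1.003 (camera, adjusted p = 0.00548). With an estimated correlation the adjusted p was 0.736, and with fry it was 0.615. No member passed over all genes or adjusted over the list alone. Cxcl10, a chemokine for activated T cells, was at 60.7 ± 26.3 TPM in the adjuvant group and 144 ± 101.1 TPM in the vaccine group (limma adjusted p = 0.412). Irgm1, an interferon-induced GTPase, was at 40.8 ± 16.2 and 78.7 ± 47.0 TPM (adjusted p = 0.437). Vaccine 3 held the highest level of this list, 6.14 against 3.21 to 4.79 in the other libraries. Adjuvant 1, at 4.79, lay above vaccine 1 (4.10) and vaccine 2 (4.56), and the exact two-sided permutation p was 0.3. The call ended without vaccine 3 (adjusted p = 0.228) and without adjuvant 3 (adjusted p = 0.0582). Ptprc, which encodes the leukocyte antigen CD45, was also highest in vaccine 3, at 18.6 TPM against 4.61 to 11.98 TPM in the other libraries, and the level of the list ran in the same order as Ptprc over all 6 (Spearman correlation 1). The mean log2 difference of the list was 1.04 and fell to 0.437 without vaccine 3.

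Lymphocyte and antigen presentation lists were higher in the vaccine group on average and did not pass on the TPM scale. The T cell list had 10 of 11 genes higher (median 0.34, adjusted p = 0.605), with a level of 3.44 in vaccine 3 and 1.53 to 2.39 in the other libraries. The CD8 and cytotoxic effector list had 10 of 10 genes higher (median 0.50, adjusted p = 0.241), with Gzmb at 5.81 ± 3.27 and 9.51 ± 3.17 TPM and Prf1 at 3.003 ± 0.631 and 4.24 ± 1.03 TPM. The NK cell list (3 of 5 genes higher, median 0.80, adjusted p = 0.665), the checkpoint and exhaustion list (5 of 6, 0.22, 0.642) and the regulatory T cell list (3 of 4, 0.52, 0.614) did not pass either. MHC class I presentation had 11 of 13 genes higher (median 0.41, adjusted p = 0.332) and MHC class II presentation 9 of 9 (median 0.78, adjusted p = 0.05001). The type I interferon response had 13 of 17 genes higher (median 0.22, adjusted p = 0.728). Without vaccine 3, the mean log2 difference fell from 0.366 to -0.182 for the T cell list, from 0.498 to 0.122 for CD8, from 0.539 to 0.226 for NK, from 0.275 to -0.0752 for checkpoint, from 0.32 to 0.17 for regulatory T cell, from 0.35 to -0.004 for MHC class I and from 0.216 to 0.0287 for type I interferon. It was highest without vaccine 1 for T cell (0.736), checkpoint (0.512), regulatory T cell (0.426) and MHC class I (0.614). For CD8 (0.798), NK (0.872) and type I interferon (0.429) it was highest without adjuvant 1. Without vaccine 3, the direction of the test turned for the T cell (adjusted p = 0.154), CD8 (0.823), checkpoint (0.278), regulatory T cell (0.816), MHC class I (0.246) and type I interferon (0.348) lists. The B and plasma cell list had 4 of 4 measured genes higher (median 0.77, adjusted p = 0.0931), of which Jchain and Igkc passed adjusted over the list alone. Jchain, which joins secreted IgM and IgA, was at 3.05 ± 0.947 and 5.56 ± 0.558 TPM, and Igkc, the kappa light chain constant region, at 34.6 ± 8.78 and 87.2 ± 43.7 TPM. The lymphoid chemokine and stroma list had 3 of 3 measured genes higher (median 0.76, adjusted p = 0.0931). With median-of-ratios scaling the MHC class II (adjusted p = 0.00679), B and plasma cell (0.03795) and lymphoid chemokine (0.0422) lists passed, and MHC class II also passed with upper-quartile scaling (0.01185) and on the protein-coding scale (0.0444). The B and plasma cell list missed in both of these (camera adjusted p = 0.05046 and 0.502). Its median was 0.105 in the second, which leaves out Igkc as not protein-coding, so its members differed there. The lymphoid chemokine list also missed in both (0.0597 and 0.1003). On the TPM scale the adjusted p with an estimated correlation was 0.736 for MHC class II and 0.653 for each of the other 2 lists. The mean log2 difference of MHC class II was 0.72, fell to 0.271 without vaccine 3 and rose to 1.11 without vaccine 1.

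Myeloid lists did not pass on the TPM scale, but several of their members did adjusted over the list alone. The neutrophil list had 7 of 8 genes higher (median 0.55, adjusted p = 0.0931), with the C-type lectin receptor genes Clec4d at 8.38 ± 1.46 and 14.5 ± 0.931 TPM and Clec4e at 1.71 ± 0.401 and 3.84 ± 0.728 TPM. The dendritic cell list had 7 of 8 genes higher (median 0.36, adjusted p = 0.0931), with the chemokine gene Ccl17 at 7.23 ± 1.25 and 13.0 ± 0.75 TPM. In the macrophage list, 10 of 14 genes were higher and the adjusted p was 0.770. The median of this list was 0.09 while camera gave the lower direction. Its member Arg1, the arginase of alternatively activated macrophages, was at 57.0 ± 6.78 and 105.6 ± 30.03 TPM, and Folr2, a marker of tissue-resident macrophages, at 25.6 ± 6.30 and 14.9 ± 1.51 TPM. The mast cell list had 6 of 6 genes higher (median 1.06, adjusted p = 0.0931) and no member that passed. With median-of-ratios scaling the dendritic cell (adjusted p = 0.0319), neutrophil (0.0319) and mast cell (0.03795) lists passed, and with upper-quartile scaling none of the 3 did (0.05046 each), nor on the protein-coding scale (0.1003, 0.1149 and 0.1003). On the TPM scale their adjusted p with an estimated correlation was 0.736, 0.653 and 0.736. The mean log2 difference of the neutrophil list was 0.65 and fell to 0.324 without vaccine 1, that of the dendritic cell list was 0.35 and fell to 0.215 without vaccine 3, and that of the mast cell list was 0.837 and ranged from 0.57 to 1.3 without 1 library. The libraries of the 2 groups did not overlap for 6 lists, all higher in the vaccine group, where chance gives 3.1 of 31. These were the inflammatory cytokine, lymphoid chemokine, regulatory T cell, B and plasma cell, neutrophil and dendritic cell lists, and the smallest adjusted exact permutation p was 0.517. Without adjuvant 1 there were 13 such lists. With a library fewer, chance separates a larger share, so the 3.1 is no measure for them.

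**Figure D3:**
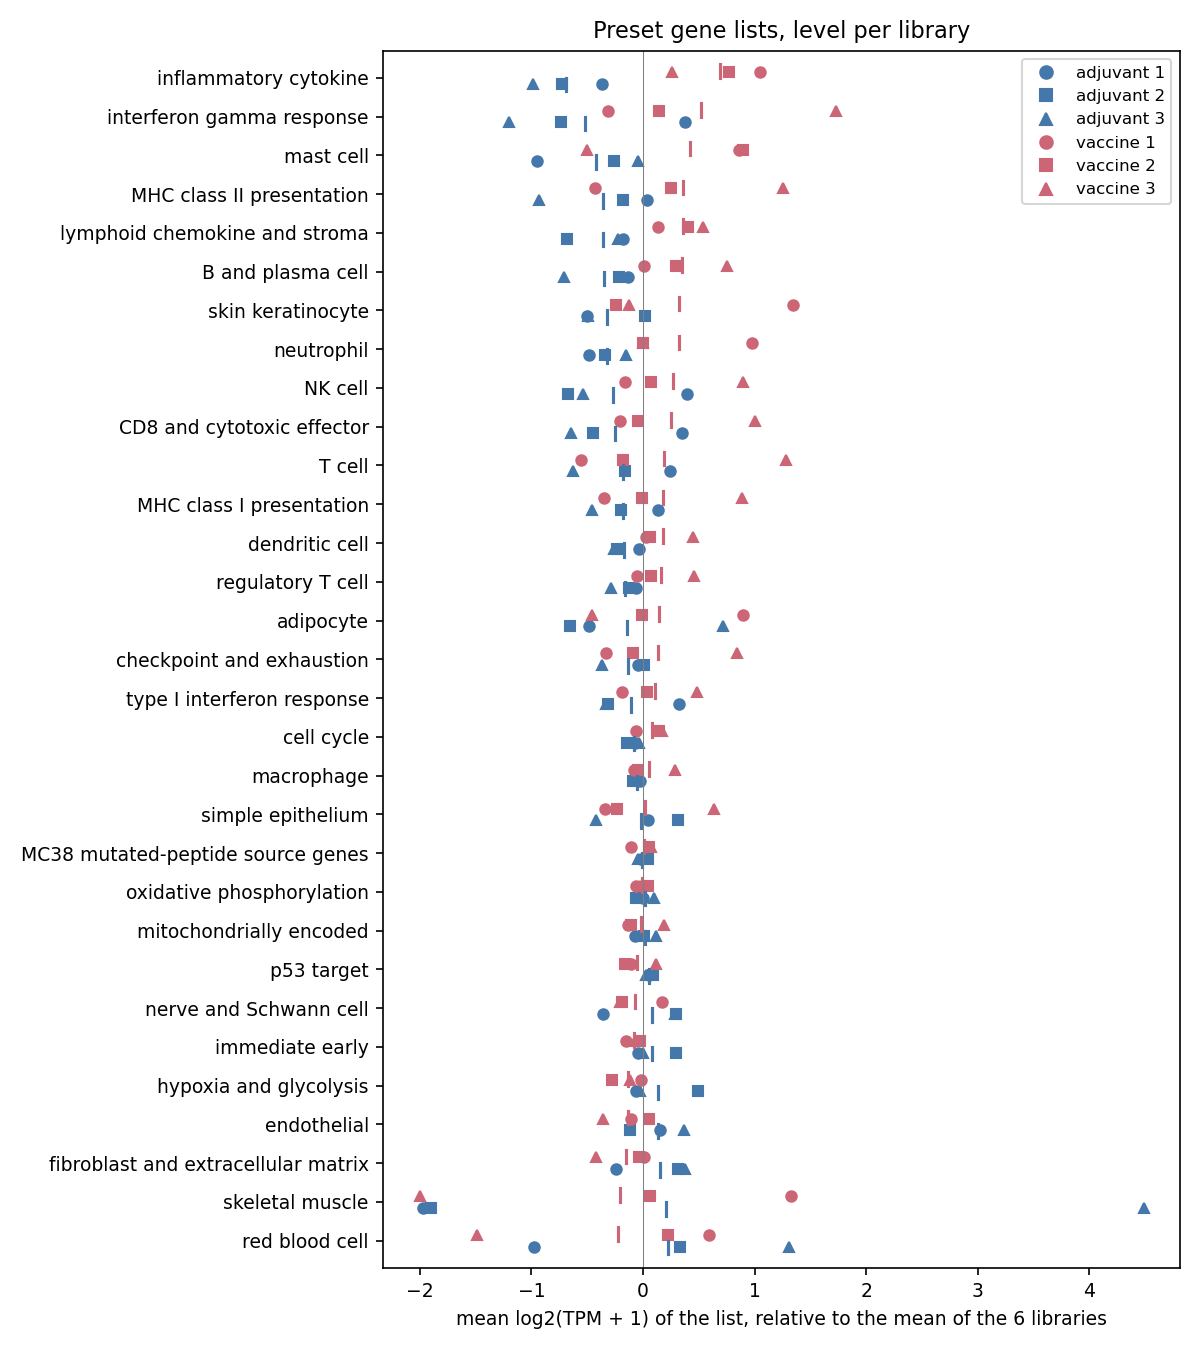
Mean log2(TPM + 1) of the measured genes of each of the 31 preset lists, relative to the mean of the 6 libraries (horizontal axis), with 1 point per library and a vertical tick at each group mean. The vaccine libraries lie above all adjuvant libraries for the inflammatory cytokine list, vaccine 3 is highest for the interferon gamma and T cell lists, and adjuvant 3 is highest for the skeletal muscle list.

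Lists of glycolytic and hypoxia-induced genes, of stromal matrix genes and of endothelial genes passed as lower in the vaccine group, with the preset correlation only. In the hypoxia and glycolysis list, 17 of 18 genes were lower (median log2 difference -0.26, camera adjusted p = 3.96e-06, and 0.653 with an estimated correlation). Its level was 7.317 in adjuvant 2 and 6.548 to 6.807 in the other libraries, and without adjuvant 2 its adjusted p was 0.0187. The KEGG sets of glycolysis (22 of 40 genes lower, adjusted p = 0.0851) and HIF-1 signalling (44 of 88, 0.2003) did not pass. Aldoa of the hypoxia list, a glycolytic aldolase, was at 1036 ± 231 TPM in the adjuvant group and 759 ± 56.5 TPM in the vaccine group, and Adm at 4.47 ± 0.288 and 2.60 ± 0.892 TPM, and neither passed. The fibroblast and extracellular matrix list had 14 of 18 genes lower (median -0.32, adjusted p = 1.49e-05, and 0.653 with an estimated correlation). Col1a1, a chain of type I collagen, was at 132 ± 22.3 and 79.9 ± 6.30 TPM and passed adjusted over the list alone. Fibronectin (Fn1) was at 586 ± 124 and 350.0 ± 89.5 TPM and did not pass. The endothelial list had 13 of 14 genes lower (median -0.26, adjusted p = 2.09e-05, and 0.653 with an estimated correlation), and Cldn5, a tight junction gene of endothelium, was at 7.88 ± 0.322 and 4.04 ± 0.868 TPM and passed adjusted over the list alone. The groups overlapped in the per-library level of each of these 3 lists, with an exact two-sided permutation p of 0.3. These calls held without any 1 library, but their size did not. The mean log2 difference of the hypoxia list was -0.271, shrank to -0.0918 without adjuvant 2 and grew to -0.369 without adjuvant 1. That of the fibroblast list was -0.299, shrank to -0.164 without vaccine 3 and grew to -0.495 without adjuvant 1. That of the endothelial list was -0.273, shrank to -0.157 without adjuvant 3 and grew to -0.4 without adjuvant 2. The level of the fibroblast list ran in the opposite order to Ptprc over all 6 libraries (Spearman correlation -1), with adjuvant 1 below vaccine 1 and vaccine 2. In all, 5 of 31 lists passed, and the count was 9 without adjuvant 2, 12 without vaccine 1 and 12 without vaccine 2.

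Lists of cell state did not pass on the TPM scale. The cell cycle list had 17 of 20 genes higher (median 0.18, adjusted p = 0.05001), and Ccna2, cyclin A2, was at 108 ± 3.41 and 145 ± 4.55 TPM and passed adjusted over the list alone. The p53 target list had 8 of 13 genes lower (median -0.04, adjusted p = 0.0641), with Gdf15 at 5.40 ± 0.862 and 2.82 ± 0.306 TPM, past the threshold over the list alone. The immediate early list had 7 of 12 genes lower (median -0.16, adjusted p = 0.0708), and Atf3, a stress-induced transcription factor, was at 25.7 ± 6.59 and 8.87 ± 2.62 TPM and passed adjusted over the list alone. Both of these lists, the neutrophil list and the inflammatory cytokine list passed fry's test for change in either direction. The oxidative phosphorylation list had 11 of 16 genes lower (median -0.01, adjusted p = 0.05001) and the mitochondrially encoded genes 3 of 9 (median 0.06, mean -0.03, camera direction lower, adjusted p = 0.728). On the protein-coding scale the cell cycle, p53 target and oxidative phosphorylation lists passed (adjusted p = 0.0444 each), and the last also passed with median-of-ratios (0.01036) and upper-quartile scaling (0.0127). On the TPM scale their adjusted p with an estimated correlation was 0.736, 0.653 and 0.731. With median-of-ratios and upper-quartile scaling the cell cycle list missed (camera adjusted p = 0.125 and 0.0996), with medians of 0.08 and 0.102. The p53 target list missed in both as well (0.078 and 0.0753). The mean log2 difference of the oxidative phosphorylation list turned without adjuvant 3 (0.0152), that of the p53 target list fell from -0.106 to -0.0515 without vaccine 2, and that of the immediate early list from -0.167 to -0.059 without adjuvant 2. The source genes of known MC38 mutated peptides had 3 of 6 higher (median 0.03, camera direction lower, adjusted p = 0.596).

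Genes of tissues next to the tumour varied between libraries. The muscle actin gene Acta1 was at 719 TPM in adjuvant 3, 74.4 TPM in vaccine 1, 26.8 TPM in vaccine 2 and 0.21 TPM or less in the other libraries. The skeletal muscle list had 12 of 14 genes lower in the vaccine group (median -0.37, adjusted p = 0.0931), and its direction turned without adjuvant 3 (adjusted p = 0.197). The red blood cell list had 5 of 5 genes lower (median -0.46, adjusted p = 0.0931), but its mean log2 difference of -0.446 turned to 0.0982 without adjuvant 3 and to 0.185 without vaccine 3, and was -1.05 without adjuvant 1. The skin keratinocyte list had 3 of 3 genes higher (median 0.51, adjusted p = 0.225), with Sbsn at 17.3 TPM in vaccine 1 and 3.23 to 6.59 TPM in the other libraries, and its direction turned without vaccine 1 (adjusted p = 0.933). The adipocyte list (median 0.12, adjusted p = 0.728), the nerve and Schwann cell list (median 0.01, mean -0.15, 0.332) and the simple epithelium list (median -0.15, mean 0.04, 0.965) did not pass, and without 1 library the mean log2 differences of the adipocyte and nerve lists were -0.0913 to 0.714 and -0.369 to -0.0418. With the skeletal muscle level as a covariate, limma called 2 genes and camera 6 lists.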

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

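The stricter filter, the pseudocounts, the fit without a variance trend, the protein-coding scale, the muscle covariate and the fit to 4 libraries were chosen after seeing the data. Both genes were also called after each scaling, with the stricter filter, with either pseudocount, with quality weights, without the variance trend and with the muscle covariate. Counts of calls, in the order genes (2), preset lists (5), KEGG sets (9) and lists whose libraries do not overlap (6), moved by over 1.5 times as follows, and the cause was not tested except where given. Median-of-ratios scaling gave 12 lists and 21 sets, and upper-quartile scaling 15 sets. With no filter on low values limma called 0 genes of 27554 (2095 at an unadjusted p under 0.05), 9 lists and 47 sets, where more genes were tested. The stricter filter gave 3 lists whose libraries did not overlap. Quality weights gave 26 genes (2 shared) and 8 lists. Pseudocounts of 0.1 and 5 gave 4 genes (2 shared) and 9 lists. Without the variance trend 6 genes passed (2 shared). On the protein-coding scale, which leaves out other gene types such as Gm45236 and Igkc, 1 gene and 9 lists passed. Without adjuvant 3 and vaccine 1, limma called 0 genes (596 at an unadjusted p under 0.05), 9 lists and 31 sets. An adjusted p of 0.1 gave 4 genes. The estimated correlation and fry each gave 0 lists and 0 sets. Without 1 library each, there were 0 to 44 genes, 6 to 12 lists, 6 to 42 sets and 5 to 13 lists whose libraries did not overlap. With a library left out, chance separates more lists than in the full comparison.

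The replicate numbers, used as a block, gave 0 genes (1628 at an unadjusted p under 0.05), 5 lists and 8 sets, without the Fanconi set (adjusted p = 0.0843). Same-numbered libraries did not clearly deviate together (correlations of -0.0656, 0.116 and -0.229), and not every library correlated best with its own number. Some library measures did follow the numbers. The share of mitochondrially encoded genes in libraries 1, 2 and 3 was 7.04%, 5.47% and 6.68% (adjuvant) and 7.11%, 5.73% and 6.92% (vaccine). Genes above 0 ran in the same order (21686, 21037 and 21526, and 22052, 21434 and 21994). Ptprc and the share of ribosomal protein genes did not. With 3 libraries per group these values can neither exclude nor establish pairing or a shared batch, which the labels do not state either way. With this block the direction turned for simple epithelium and the mitochondrially encoded genes (adjusted p = 0.9695 for both).

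Direction also turned in these lists, none of which passed in either setting. Simple epithelium turned with median-of-ratios (adjusted p = 0.648) and upper-quartile scaling (0.738), a pseudocount of 5 (0.891), no variance trend (0.935) and fry (0.738). Quality weights turned the checkpoint (0.917) and adipocyte (0.996) lists. Without adjuvant 3 and vaccine 1, macrophage (0.402), skin keratinocyte (0.815), skeletal muscle (0.645) and mitochondrially encoded genes (0.477) turned. With fry, macrophage (0.713), mitochondrially encoded genes (0.769) and the MC38 mutated-peptide source genes (0.889) turned. Lists that turned without some 1 library had adjusted p-values, over all 6 such fits, of 0.0279 to 0.881 (T cell), 0.0482 to 0.823 (CD8), 0.102 to 0.854 (checkpoint), 0.573 to 0.899 (regulatory T cell), 0.135 to 0.881 (macrophage), 0.00198 to 0.854 (MHC class I), 0.121 to 0.870 (type I interferon), 0.358 to 0.823 (simple epithelium), 0.0433 to 0.933 (skin keratinocyte), 0.000528 to 0.723 (skeletal muscle), 0.103 to 0.987 (adipocyte) and 0.175 to 0.933 (mitochondrially encoded). Log2 differences of single genes that turned were -1.955 to 0.597 (Tnni2), -1.301 to 0.0494 (Hbb-bs) and -0.496 to 0.0336 (Alas2) without 1 library, and 0.0443 for Tnni2 in the 4 libraries. The count-based fits planned before the data were examined were not run, because the values are TPM, and the stricter filter planned then is the same as the main one. The depth is unknown, so what it limits could not be given.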

Other observations

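Of the tests here, the counts of lists and sets over other splits and the order of muscle genes were chosen only after the result was seen, as were the patterns themselves. The count of genes over other splits was planned with the count-based fit, but how to read it was set after the result was seen. Without adjuvant 1, 44 genes passed, and no groups among them were tested. They included Hmgcs1, Idi1, Sqle, Msmo1, Cyp51 and Sc5d, which act in cholesterol synthesis. They also included the chemokine genes Ccl2 (log2 difference 2.04), Ccl7 (1.72) and Ccl12 (1.25) and the receptor gene Ccr2 (1.60). Lower in that fit were the glucocorticoid-induced genes Per1 (-2.48) and Tsc22d3 (-1.325), and the matrix genes Col1a1 (-0.84) and Cilp (-1.76). With all 6 libraries Ccr2 was at 5.97 ± 2.83 TPM in the adjuvant group and 15.3 ± 2.08 TPM in the vaccine group, and no call followed.

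Some single genes of fatty acid synthesis and sterol sensing were also higher in the vaccine group, but the KEGG sets of fatty acid biosynthesis (10 of 15 genes higher, camera adjusted p = 0.5435) and of unsaturated fatty acids (14 of 20, 0.2083) did not pass. Fasn, the fatty acid synthase, was at 37.4 ± 2.88 and 54.4 ± 4.45 TPM, Scd2 at 114 ± 19.6 and 187 ± 26.6 TPM, Insig1 at 52.4 ± 6.55 and 80.9 ± 5.80 TPM, and Srebf2 at 58.1 ± 7.73 and 80.9 ± 5.74 TPM. None passed over all genes. They belong to a list of 13 measured targets of the SREBP transcription factors, written before their values were seen. Of these 12 were higher, with a median log2 difference of 0.444, and the highest of the other 9 splits was 0.258. The list was written because sterol genes had been seen to differ between these same libraries. Targets that vary with those genes would then peak at the real split, whatever set the tumours apart. The splits show that the targets moved together with the sterol genes. They cannot tell the vaccine from a difference between single tumours. A hypothesis is that SREBP activity was higher in these tumours after the vaccine, which may involve tumour or immune cells.

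The higher sterol genes were weighed against 3 technical explanations. Scaling the libraries otherwise left the median log2 difference of the 15 steroid biosynthesis genes at 0.491 or more (0.453 to 0.518 without 1 library), against 0.588. These scalings moved the median of all genes only from 0.0925 to 0.0193 or -0.000946. They could hardly have removed a difference of 0.588, so this was no real test. The values show only that the difference exceeds that shift. With the skeletal muscle level as a covariate the median of the 15 genes was 0.58 (0.515 to 0.635), and with the level of Ptprc, for leukocytes, 0.509 (0.413 to 0.568). These covariates argue against muscle and the level of Ptprc as the whole cause. Ptprc is 1 gene for all leukocytes, so a change in the kinds of leukocytes present is left open. The vaccine itself stays open as a hypothesis, as do a change in the tumour cells and a batch, since the labels give no batch.

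The higher inflammatory cytokine genes, with a median log2 difference of 1.32, had one of 1.28 after other scalings (1.12 to 1.62 without 1 library), 1.34 with the muscle level as a covariate (0.67 to 1.67) and 1.33 with Ptprc (0.953 to 2.24). The size thus depends on single libraries, but it stayed above the 0.5 set beforehand. The scalings move all genes by a small amount, as given above, so they could hardly have removed a difference of 1.32. The covariates argue against muscle and the level of Ptprc as the whole cause. Ptprc is 1 gene for all leukocytes, and its rank correlation with the level of this list was 0.486. A change in the kinds of leukocytes present is therefore left open. With the neutrophil list level as a covariate, a test written after those levels but before its result were seen, the median was 0.788 (0.623 to 1.79 without 1 library), but that level separates the groups by itself, so more neutrophils and higher cytokine genes per cell cannot be told apart. The vaccine, in either way, stays open as a hypothesis.

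Skeletal muscle genes were high in adjuvant 3, vaccine 1 and vaccine 2, which are in both groups. All 14 of the 14 measured genes of the list were highest in adjuvant 3 and next highest in vaccine 1, as muscle in the tumour piece would give, with Acta1 at 719 TPM and Tnni2 at 275 TPM in adjuvant 3. No biological explanation was tested.

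A hypothesis that the lower Ddit3, Atf3 and Gadd45a reflect a weaker integrated stress response was tested on 14 other genes of that response, of which 10 were lower. Their median log2 difference was -0.133 (-0.253 to 0.0534 without 1 library), under the size set beforehand, so they did not follow as a list. A hypothesis that the lower Pi16 and Fbln1 reflect fewer adventitial fibroblasts was tested on 11 other genes of these cells, of which 5 were lower, with a median of 0.05 (-0.099 to 0.17 without 1 library), so they did not follow as a list either. The lower ones included Dpt (-0.355) and Col14a1 (-0.58). The 6 higher ones included Ly6a and Cd34, at 1205 and 660 TPM in the adjuvant group. RNA of whole tumour pieces does not tell which cells such transcripts came from. The list therefore cannot decide whether these fibroblasts were fewer. A hypothesis that lower Per1, Tsc22d3 and Angptl4 reflect weaker glucocorticoid signalling was tested on 8 other target genes, written before their values were seen. All 8 were lower, with a median of -0.441 (-0.614 to -0.337 without 1 library), among them Klf9 at 27.9 ± 7.68 and 14.6 ± 2.97 TPM and Mt1 at 1316 ± 286 and 852 ± 67.4 TPM. Another split of the libraries gave a larger size, 0.486, so this may be a difference between single tumours and cannot be told apart from one.

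Of all genes in the table, 6 were listed at 0 in all libraries of 1 group and at 1 TPM or more in all of the other, among them Gm45236 and Defb25, and the other splits gave 1 to 9 such genes. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 2 genes past the threshold and the highest other split 4, and 5 of the 10 gave as many as the real one. For preset lists it gave 5 and the highest other 16, with 9 of 10 giving as many, and for KEGG sets 9 and 54, with 9 of 10. At an unadjusted p under 0.05 on the TPM scale, the real split gave the most genes, 1638, against 121 to 1469 in the others. After median-of-ratios scaling the real split gave 1373, and the other splits were not rescaled. With only 10 splits, first place cannot give a share under 0.05. For lists and sets, some splits gave several times the real count. Whether this reflects a structure of the libraries other than the groups was not tested.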
